A study of Drosophila melanogaster with 20 samples.

How the data were processed

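Total RNA from heads of adult Drosophila melanogaster was measured on 20 single-colour arrays (Cy3 label), 1 array per sample, with 8 genotypes forming 4 pairs of an experimental and a control genotype. The labelling was done by the array maker, NimbleGen, per the labels' protocols. The deposited values are log2 RMA levels: RMA, a method that corrects background, normalizes between arrays and summarizes the probes of a transcript on a log2 scale, is named in the submitters' processing notes without a version. The probes per transcript, the probe filter, the annotation release and the background step are not given in the sources used here. That the scale is log2 was read from the values, whose lowest value per array lay between 4.31 and 4.89 and whose highest lay between 15.75 and 15.99. The authors did not pool replicates, and the table held 15473 transcripts with 0 missing values.

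The 20 arrays had 2 distributions of values. The medians of the 8 ATM8 and Repo arrays lay between 10.45 and 10.63, with SDs from 2.78 to 2.80, and the medians of the 12 Elav and ElavC155 arrays lay between 10.84 and 10.93, with SDs from 2.95 to 2.99. No label says whether the arrays were normalized in 2 sets. Each of the 4 comparisons lies within 1 of these sets, while the differences of effects between Repo and either neuronal driver set one against the other. RMA levels carry no detection flag, so a fold change from a dim level has no measured floor, and the number of arrays limits the precision.

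Each row of the table is a FlyBase transcript identifier, and the table does not pair it with a gene. The gene table used here, which follows Release 6 of the fly genome, was searched through all its name columns, and 44 rows matched a gene, 17 of them exactly 1 gene (0.11% of rows) and 27 several genes. Only the 17 are named, and none of that table's coordinates is used. None of the 488 entries in the 22 gene lists fixed before the data were examined (antimicrobial peptides, Imd and Toll pathway genes, stress genes, cell type markers and others) had a row that could be matched: the number matched was 0. The tests of these lists were therefore not run, the level of tefu, the fly ATM gene, is not analysed here, and neither are the levels of repo, elav, white and the antimicrobial peptide genes. Averaging of rows per gene, which had been planned, was replaced by a test of each transcript.

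Each transcript was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings, two-sided), with a mean for each of the 8 genotypes fitted over all 20 arrays (12 residual degrees of freedom, 3.79 prior degrees of freedom). No array was shared between comparisons. P-values were adjusted by the Benjamini-Hochberg method over 15473 transcripts, and a transcript is said to have changed, risen or fallen at an adjusted p under 0.05. A further count also asked for at least a 1.5-fold change. The difference of 2 effects was tested as an interaction contrast in the same fit, for 4 pairs of comparisons. Errors of log2 fold changes are standard errors from limma, and errors of levels are SDs between arrays. The labels call the replicates biological but do not say how they were made, so the p-values measure the spread between these samples. Replicates of a genotype correlated at 0.976 or above across transcripts, and 0 pairs held identical values.

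The rule for named transcripts, fixed before the data were examined, took in each comparison the 10 largest rises and the 10 largest falls among transcripts at an adjusted p under 0.05 whose experimental arrays all lay above, or all below, the control arrays. Because identifiers without a gene name say little, 2 rises and 2 falls per comparison are printed and the others are given as ranges. Other transcripts among the planned names could not be matched. The 17 named genes were not chosen by their values: they are those that the gene table could name.

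Overlaps of changed transcripts between comparisons were tested with Fisher's exact test per direction (12 tests, adjusted together). The transcripts changed in 1 comparison were also followed in the 3 others with limma's camera test (24 tests), with a preset inter-gene correlation of 0.01 and again with an estimated one. These camera tests were chosen after it was seen that gene names were missing. The procedure was tested on simulated data with 200 of the 15473 transcripts changed. With the design of the Repo comparison it recovered 25.8% of the 1.5-fold, 57.4% of the 2-fold and 97.3% of the 4-fold changes, and 5.38% of its calls were false. With the design of the Elav comparison it recovered 36.9%, 80.3% and 98.6%, and 10.5% of its calls were false, above the nominal 5%. The simulation drew normal noise 1 time per design from each transcript's estimated spread. It held no correlation between transcripts and no sets of replicates. It therefore cannot show that the calls of 1 design are less reliable than those of the other.

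The replicate numbers in the labels run in parallel in both genotypes of each comparison, and no label says that a number marks a shared batch. In the Elav comparison the deviations of same-numbered arrays from their group means correlated at 0.12, 0.17, 0.24 and 0.17, all above the bound of 0.1 set for taking numbers as pairs, so there the numbers were taken to pair the samples, from the data alone. Some differently numbered arrays correlated more highly, at 0.39 for Elav-ATMi replicate 4 with control replicate 3 and 0.24 for Elav-ATMi replicate 2 with control replicate 1, and 2 of the 4 Elav-ATMi arrays correlated best with the control of their own number. Replicates 1 and 2 also deviated together against replicates 3 and 4: the correlations within these 2 sets were at least 0.062 and those across them at most -0.053. Pairing by number therefore cannot be told apart from these 2 sets. Alternatives tried were an intensity trend with robust settings, the replicate number as a block, quantile normalization on top of the deposited values, a common median, leaving out the dimmest 25% (3869 transcripts), array weights, a fit of only the compared arrays, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.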

Results

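Head RNA of flies with lowered ATM function was compared with that of matched control flies. ATM is the protein kinase that responds to DNA breaks, and tefu is its gene in the fly. The comparisons address whether lowered ATM function alters gene expression in the head, and in which cell type the lowering has that effect. In the first comparison, 2 samples of ATM8 homozygotes were set against 2 of ATM8 heterozygotes. ATM8 is a temperature-sensitive allele, and the flies of both genotypes were reared at 18°C and held for 3 days at 25°C. Any variants linked to the allele go together with it in this comparison. Their effects cannot be told apart from those of the allele. In the 3 others, a GAL4 driver activated an RNA interference transgene against ATM, and the controls carried the driver without that transgene, so that RNA interference and presence of the transgene go together. The Repo driver acts in glia (2 samples against 2), the Elav driver on chromosome 2 in neurons (4 against 4) and the ElavC155 driver on the X chromosome also in neurons (2 against 2). All RNA interference flies and their controls were kept at 25°C. Flies of all genotypes were collected at 0 to 3 days of age and held for 3 days. The labels give an age of 4 to 6 days for the RNA interference flies and their controls, and none for the ATM8 flies. The RMA levels (log2) of 15473 transcripts were analysed, identified by FlyBase number, and 17 of them could be tied to a single named gene.

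In ATM8 homozygotes, 246 transcripts changed, 147 upward and 99 downward. The largest rise was that of FBtr0080464, from 7.71 ± 0.39 in heterozygotes to 13.63 ± 0.57 in homozygotes (SD, n = 2 each), a log2 fold change of 5.92 ± 0.36 (SE, limma adjusted p = 1.2e-07). FBtr0073937 rose by 4.08 ± 0.22 (adjusted p = 3.5e-08). FBtr0082093 fell by 5.84 ± 0.26, from 12.19 to 6.35 (adjusted p = 3.9e-09), and FBtr0082765 fell by 4.39 ± 0.38, to 9.18 ± 1.4 in homozygotes (adjusted p = 8.7e-06). The 10 largest rises spanned 2.43 to 5.92 and the sizes of the 10 largest falls 2.23 to 5.84 on the log2 scale. At least a 4-fold change was measured for 14 transcripts that rose and 14 that fell, and 233 of the changed transcripts passed 1.5-fold.

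Among the 17 named genes in ATM8 homozygotes, 0 changed in limma when adjusted over all transcripts, and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 1 passed. This was mio, which encodes a component of the GATOR2 complex that regulates TORC1, with a log2 fold change of -0.66 ± 0.18 (adjusted p = 0.080 over all transcripts and 0.032 over the list alone). Its adjusted p was 0.044 after quantile normalization and ranged up to 0.38 over the other settings. LanA, a laminin alpha chain, had a log2 fold change of 0.51 ± 0.21 (adjusted p = 0.29). The count of changed transcripts rested on every array: it was 132 without heterozygote replicate 1, 98 without heterozygote replicate 2 (47 upward and 51 downward, so that rises no longer outnumbered falls), 114 without homozygote replicate 1 and 121 without homozygote replicate 2. In a fit of these 4 arrays alone it was 119.

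RNA interference with the glial driver changed 658 transcripts, 451 upward and 207 downward. FBtr0070073 rose most, from 7.08 ± 1.6 in Repo-GAL4 controls to 14.51 ± 0.11 in Repo-ATMi flies (SD, n = 2 each), a log2 fold change of 7.43 ± 0.64 (limma adjusted p = 3e-06). FBtr0081033 rose 32.1-fold (SE 0.44 on the log2 scale, adjusted p = 3.5e-06) and FBtr0079509 fell by 3.49 ± 0.28 (adjusted p = 1.6e-06). FBtr0076983 fell by 3.44 ± 0.78 (adjusted p = 0.018), with levels of 5.37 and 7.41 in the Repo-ATMi samples against 9.47 and 10.19 in controls. Its call was lost without control replicate 1 (adjusted p = 0.067), control replicate 2 (0.16) or Repo-ATMi replicate 1 (0.24), while its adjusted p lay between 0.007 and 0.048 under the other settings. The 10 largest rises spanned 3.28 to 7.43 and the sizes of the 10 largest falls 2.14 to 3.49. At least a 4-fold change was measured for 52 transcripts that rose and 11 that fell, and 601 passed 1.5-fold.

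Of the 17 named genes with the glial driver, 0 changed in limma over all transcripts, 0 passed when adjusted over the list alone, and 4 had an unadjusted p under 0.05. The log2 fold changes of these 4 were -0.48 ± 0.21 for Fatp1, a fatty acid transport protein (adjusted p = 0.24), -0.42 ± 0.19 for HDAC3, a histone deacetylase (0.26), -0.36 ± 0.15 for CG16974 (0.21) and 0.27 ± 0.12 for Wdr24, a GATOR2 component (0.28). The count of 658 fell to 266 without control replicate 1, 262 without control replicate 2 and 269 without Repo-ATMi replicate 1, and rose to 1118 with array weights.

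**Figure D1:**
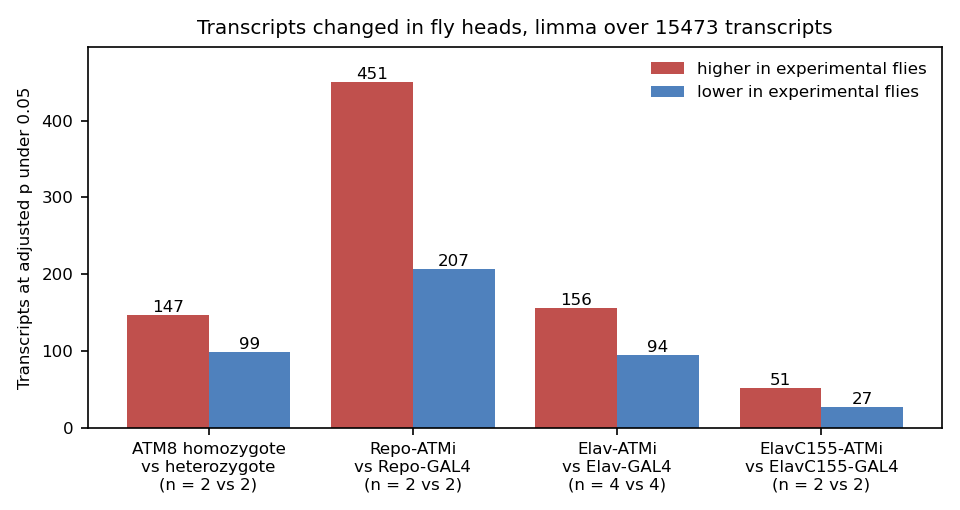
Number of transcripts at a limma adjusted p under 0.05 (vertical axis) in each of the 4 comparisons, with red bars for transcripts higher and blue bars for transcripts lower in the experimental flies. The glial driver gave 451 higher and 207 lower transcripts, and the ElavC155 driver 51 and 27.

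RNA interference with the neuronal Elav driver changed 250 transcripts, 156 upward and 94 downward. FBtr0070073 again rose most, from 5.83 ± 0.98 in Elav-GAL4 controls to 13.59 ± 0.29 in Elav-ATMi flies (SD, n = 4 each), by 7.75 ± 0.45 on the log2 scale (limma adjusted p = 3.5e-08). FBtr0078518 rose by 4.08 ± 0.22 (adjusted p = 1.7e-08). FBtr0072462 fell by 5.40 ± 0.26, from 10.90 to 5.50 (adjusted p = 3.4e-09), and FBtr0076962 fell by 2.94 ± 0.27 (adjusted p = 6.8e-06). The 10 largest rises spanned 3.18 to 7.75 and the sizes of the 10 largest falls 1.87 to 5.40. At least a 4-fold change was measured for 41 transcripts that rose and 8 that fell, and 218 passed 1.5-fold.

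Among the 17 named genes with the Elav driver, 0 changed in limma over all transcripts, 0 passed when adjusted over the list alone, and 1 had an unadjusted p under 0.05. This was CG31178, with a log2 fold change of -0.58 ± 0.24 (adjusted p = 0.44). With the replicate number as a block its adjusted p was 0.037, and over the other settings it ranged from 0.16 to 0.71. The 250 changed transcripts became 143 when the dimmest 25% was left out and 115 in a fit of the 8 Elav arrays alone. The count was 137 among replicates 1 and 2 of both genotypes, 171 among replicates 3 and 4, and 337 with these 2 sets as a block.

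The ElavC155 driver, also neuronal, changed 78 transcripts, 51 upward and 27 downward, and all 78 passed 1.5-fold. FBtr0070073 rose by 8.93 ± 0.64, from 5.34 ± 0.34 to 14.27 ± 0.09 (SD, n = 2 each, limma adjusted p = 9.4e-07). FBtr0072463 rose by 3.52 ± 0.25 (adjusted p = 9.4e-07), and this call was lost in a fit of the 4 ElavC155 arrays alone (adjusted p = 0.052), the highest value over its settings. FBtr0082093 fell by 5.73 ± 0.26 (adjusted p = 5.3e-09) and FBtr0072462 by 5.46 ± 0.37 (adjusted p = 8e-07). The 10 largest rises spanned 1.92 to 8.93 and the sizes of the 10 largest falls 1.82 to 5.73. At least a 4-fold change was measured for 8 transcripts that rose and 4 that fell.

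Of the 17 named genes with the ElavC155 driver, 0 changed in limma over all transcripts, 0 passed when adjusted over the list alone, and 1 had an unadjusted p under 0.05: Wdr24, with a log2 fold change of -0.31 ± 0.12 (adjusted p = 0.59). The count of 78 was 6 in a fit of the 4 ElavC155 arrays alone (3 upward and 3 downward) and 194 with array weights, and it was 36 without control replicate 2, 44 without ElavC155-ATMi replicate 1 and 32 without ElavC155-ATMi replicate 2. In the last of these fits 11 rose and 21 fell, so that the excess of rises turned into an excess of falls.

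**Figure D2:**
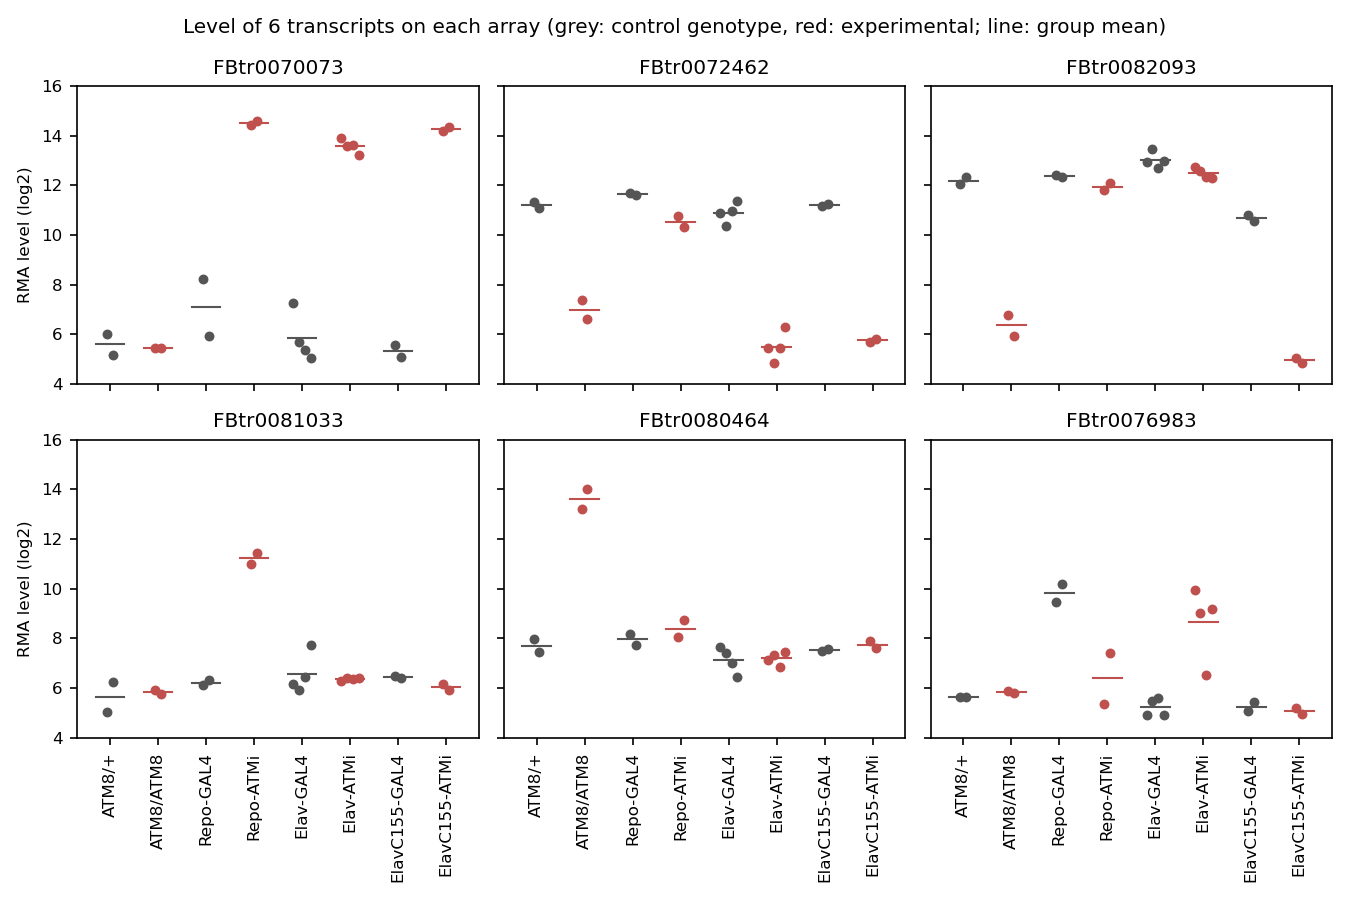
RMA level (log2, vertical axis) of 6 transcripts on each of the 20 arrays, with 1 point per array, control genotypes in grey, experimental genotypes in red and a line at each group mean. FBtr0070073 lay between 13.22 and 14.58 in all RNA interference samples and at 8.23 or below in all other samples, and FBtr0076983 was lower in Repo-ATMi flies and higher in Elav-ATMi flies than in their controls.

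The differences between effects were tested directly. The glial effect differed from the Elav effect for 279 transcripts, more positive with the glial driver for 176 and more negative for 103. FBtr0081033, which rose 32.1-fold with the glial driver, had a log2 fold change of -0.19 ± 0.31 with the Elav driver, and the difference of 5.20 passed (limma adjusted p = 4.9e-05). FBtr0076983 fell by 3.44 with the glial driver and rose by 3.45 ± 0.55 with the Elav driver, a difference of -6.89 (adjusted p = 0.00065). Its control levels also differed: 9.83 in Repo-GAL4, against 5.22 in Elav-GAL4, 5.25 in ElavC155-GAL4 and 5.65 in ATM8 heterozygotes. The Elav-ATMi samples ran from 6.54 to 9.93. Opposite responses of the 2 cell types cannot be told apart here from a difference between strains. The count of 279 was 161 without Repo-GAL4 replicate 1, 134 without Repo-GAL4 replicate 2, 143 without Repo-ATMi replicate 1 and 183 in a fit of the compared arrays alone.

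The glial effect differed from the ElavC155 effect for 147 transcripts, more positive with the glial driver for 104 and more negative for 43. FBtr0082093 had a log2 fold change of -0.43 ± 0.26 with the glial driver against -5.73 with the ElavC155 driver, a difference of 5.30 (adjusted p = 3.1e-06). For this transcript a difference between strains cannot be told apart from one between the drivers. The count was 351 with array weights, 74 and 71 without Repo-GAL4 replicate 1 or 2, 80 without ElavC155-GAL4 replicate 2, and 82 and 94 without ElavC155-ATMi replicate 1 or 2. Without ElavC155-GAL4 replicate 1 it was 166, with 85 more positive and 81 more negative.

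The effects of the neuronal drivers differed from each other for 15 transcripts, more positive with ElavC155 for 5 and more negative for 10. FBtr0082093 fell by 5.73 with ElavC155 and had a log2 fold change of -0.52 ± 0.19 with Elav (adjusted p = 0.28), a difference of -5.20 (adjusted p = 4.9e-07). Its control level was 10.68 in ElavC155-GAL4 against 13.01 in Elav-GAL4, and it also fell in ATM8 homozygotes, from 12.19 to 6.35. A difference between strains therefore cannot be told apart here from one between the drivers. With the replicate number as a block the count was 31, after quantile normalization 7, with array weights 23 and in a fit of the compared arrays alone 8. It was 41 without Elav-ATMi replicate 3 (7 more positive and 34 more negative), 7 without Elav-GAL4 replicate 4, 8 without Elav-ATMi replicate 4, 6 without ElavC155-GAL4 replicate 2, and 7 and 9 without ElavC155-ATMi replicate 1 or 2. The split was 0 more positive and 9 more negative without ElavC155-ATMi replicate 2, 7 and 7 without ElavC155-GAL4 replicate 1, and 1 and 7 in the fit of the compared arrays.

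The effect in ATM8 homozygotes differed from the glial effect for 282 transcripts, more positive in the homozygotes for 103 and more negative for 179. FBtr0070073, at 5.44 ± 0.02 in homozygotes and 5.59 ± 0.59 in heterozygotes, gave a difference of -7.58 (adjusted p = 0.00018). The count was 169 without Repo-GAL4 replicate 1 and 148 without Repo-GAL4 replicate 2.

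Shared changes were set against the number that independent lists of the same lengths would share. Fisher's exact test takes transcripts as independent, which they are not. All comparisons also used the same estimate of spread for each transcript, so the lists are not independent. The p-values may therefore overstate the sharing. The ATM8 and Repo comparisons shared 30 rises, where 4.28 were expected (Fisher's exact test, adjusted p = 5.71e-17), and 4 falls, where 1.32 were expected (adjusted p = 0.0527). Transcripts that rose in ATM8 homozygotes were higher in Repo-ATMi flies in 72.1% of cases, with a median log2 fold change there of 0.26 (camera adjusted p = 1.2e-11, and adjusted p = 0.004 with an estimated correlation). In Elav-ATMi flies the same transcripts were higher in 46.3% of cases, with a median of -0.02 (camera adjusted p = 0.85). The ATM8 and Repo arrays lie in 1 of the 2 sets of values and the Elav and ElavC155 arrays in the other. Closer sharing of ATM8 with glia than with neurons therefore cannot be told apart here from the array set. Transcripts that fell in ATM8 homozygotes passed the test in Elav-ATMi flies (camera adjusted p = 0.0042, and adjusted p = 0.032 with an estimated correlation). There 59.6% were lower, with a median of -0.04 and a mean of -0.16. They did not pass in Repo-ATMi flies (camera adjusted p = 0.21, and adjusted p = 0.34 with an estimated correlation). There 62.6% were lower, with a median of -0.14 and a mean of -0.05. Whether these 2 outcomes differ was not tested, and Elav had 4 arrays per genotype against 2 for Repo. The ATM8 and Elav comparisons shared 2 rises (expected 1.48, adjusted p = 0.662) and 5 falls (expected 0.601, adjusted p = 0.000509). ATM8 and ElavC155 shared 2 rises (expected 0.485, adjusted p = 0.0922) and 5 falls (expected 0.173, adjusted p = 1.2e-06). As whole lists, neither passed in ElavC155-ATMi flies: 59.9% of the ATM8 rises were higher there, with a median of 0.05 (camera adjusted p = 0.078, and adjusted p = 0.34 with an estimated correlation), and 51.5% of the ATM8 falls were lower, with a median of -0.01 (camera adjusted p = 0.12, and adjusted p = 0.25 with an estimated correlation). FBtr0072462 was among the falls of ATM8 homozygotes, at -4.22 ± 0.37 (limma adjusted p = 8.7e-06). This transcript and FBtr0082093 were among the falls shared with ElavC155. A difference between strains cannot be told apart there from lowered ATM function. The 30 shared rises of ATM8 and Repo became 15 and 7 without ATM8 heterozygote replicate 1 or 2, 11 and 9 without homozygote replicate 1 or 2, 10 and 12 without Repo-GAL4 replicate 1 or 2, and 9 without Repo-ATMi replicate 1. With any 1 array left out, the shared falls numbered 0 to 3 for ATM8 and Repo, 1 to 5 for ATM8 and Elav (lowest without heterozygote replicate 2) and 3 to 4 for ATM8 and ElavC155.

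Between drivers, Repo and Elav shared 44 rises (expected 4.55, adjusted p = 1.53e-30) and 14 falls (expected 1.26, adjusted p = 5.16e-11), and 10 transcripts changed in opposite directions. Repo and ElavC155 shared 23 rises (expected 1.49, adjusted p = 1.03e-21) and 3 falls (expected 0.361, adjusted p = 0.00727), and 4 transcripts changed in opposite directions. Elav and ElavC155 shared 24 rises (expected 0.514, adjusted p = 4.22e-34) and 12 falls (expected 0.164, adjusted p = 5.91e-20), with 0 in opposite directions. Arrays of both neuronal drivers lie in 1 set of values and the Repo arrays in the other. Closer sharing between the neuronal drivers cannot be told apart from the array set. Across all transcripts, which are not independent replicates, the log2 fold changes correlated at r = 0.344 (Spearman's rho = 0.179) for Elav and ElavC155, 0.164 (0.175) for Repo and Elav, 0.171 (0.0679) for Repo and ElavC155, 0.192 (0.199) for ATM8 and Repo, 0.0707 (0.0803) for ATM8 and Elav, and 0.0448 (-0.0198) for ATM8 and ElavC155. The shared rises of Elav and ElavC155 numbered 11 without ElavC155-GAL4 replicate 2 and 14 and 8 without ElavC155-ATMi replicate 1 or 2, their shared falls 7 without ElavC155-GAL4 replicate 1 or either ElavC155-ATMi replicate, and the shared rises of Repo and ElavC155 were 12 without either ElavC155-GAL4 replicate and 13 and 7 without ElavC155-ATMi replicate 1 or 2. The shared falls of Repo and Elav numbered 4 and 7 without Repo-GAL4 replicate 1 or 2, 7 without Repo-ATMi replicate 1 and 9 without Elav-GAL4 replicate 3 or 4, and the 3 falls shared by Repo and ElavC155 became 1 without Repo-GAL4 replicate 1.

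**Figure D3:**
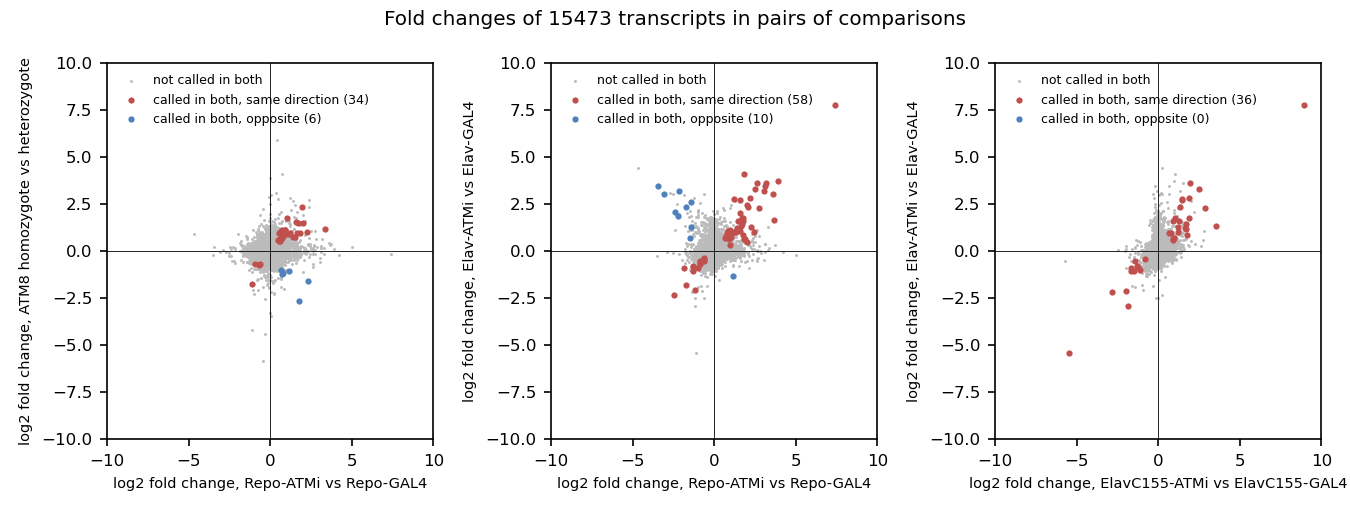
Log2 fold change of each of 15473 transcripts in pairs of comparisons, with glia against ATM8 on the left, glia against Elav in the middle and the neuronal drivers on the right. Red points changed in both comparisons in the same direction (34, 58 and 36 transcripts), blue points changed in both in opposite directions (6, 10 and 0), and grey points are all other transcripts.

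Changes in the same direction in all 3 RNA interference comparisons were found for 20 transcripts, 17 upward and 3 downward, where 0.015 and 0.0022 were expected of independent lists. FBtr0070073 was one of them. The 3 lists are not independent, since the same fit gave each transcript's estimate of spread. The count was 34 with array weights, 4 when each comparison was fitted on its own arrays, 11 and 10 without ElavC155-GAL4 replicate 1 or 2, and 11 and 7 without ElavC155-ATMi replicate 1 or 2. In ATM8 homozygotes, 9 of these 20 transcripts moved in the same direction as under RNA interference and 1 changed in the same direction past the threshold.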

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

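Of the tests in this part, those of noise and of normalization for the glial count were chosen after the counts and the fold changes had been seen, as was the use of the variance for the arrays left out. The test within replicates 1 and 2 and within replicates 3 and 4 was chosen after the counts of these sets had been seen.

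The glial driver gave 658 changed transcripts and the Elav driver 250, and the difference of their effects passed for 279. A larger sampling error in the smaller glial comparison is argued against by the variance of the log2 fold changes left after sampling variance was taken off, which was 2.74 times as large for Repo as for Elav and stayed between 2.12 and 3.88 with any 1 array of these comparisons left out. In 36 fits that used only 2 Elav arrays per genotype, the Elav count ran from 68 to 578 (median 140), the glial count from 481 to 985, and the Elav count reached the glial count in 0 fits. A difference between the 2 distributions of values is argued against by the ratio of the counts after quantile normalization of all arrays, 3.35. That step cannot undo a separate background correction or probe summary. All Repo arrays lie in 1 set and all Elav arrays in the other, so any other effect of the set cannot be told apart from the driver. An excess carried by 1 Repo array is argued against by the same variance ratio and by the lowest glial count, 262 without Repo-GAL4 replicate 2 (266 without replicate 1, 269 without Repo-ATMi replicate 1), against 220 for Elav in that fit and 250 with all arrays, a small margin with 1 sample left in a group; the cell type of the driver, the strength of the drivers and the strains crossed stay open and untested.

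The Elav comparison was set against other groupings of its 8 arrays, in a fit of these arrays alone. The real grouping gave 115 changed transcripts, the grouping of replicates 1 and 2 against replicates 3 and 4 gave 228, and the highest of all others was 0, so 2 of 35 groupings gave as many and chance is not excluded at 0.05. Among the 8 groupings that part all 4 same-numbered pairs, the highest other count was 0. So few groupings could not exclude chance at 0.05 whatever their counts, and the pairing was taken from these same data. The set of replicates 1 and 2 and the set of replicates 3 and 4 point to a structure of the samples whose origin no label gives. Each set holds 2 arrays of each genotype. A difference between the sets that is alike in both genotypes therefore cancels from the comparison and could not make its calls. Fits within each set show only whether the effect kept its direction. In them 137 transcripts changed within replicates 1 and 2 and 171 within replicates 3 and 4. Of the 70 that changed in both, 70 went in the same direction and 0 in opposite ones (exact binomial test, two-sided, p = 1.7e-21, over transcripts, which are not independent). With the sets as a block the count was 337.

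On 1 array, Elav-GAL4 replicate 2, the levels of mio (12.06, next 11.78), kis (13.83, next 14.26) and Fatp1 (14.48, next 14.03) stood apart from the 3 other control samples. These are 3 of 58 groups tested, and chance alone gives about 1 in 20. The array also had the lowest array weight, 0.359, and without it the Elav count was 231.

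Effects also differed between Repo and ElavC155 for 147 transcripts, between ElavC155 and Elav for 15, and between ATM8 and Repo for 282. For Repo minus Elav, the log2 differences were 5.20 for FBtr0081033, -3.25 for FBtr0079509, -6.89 for FBtr0076983, -2.26 for FBtr0078518 and 4.29 for FBtr0072462. For Repo minus ElavC155 they were 5.30 for FBtr0082093, 5.39 for FBtr0081033, -3.88 for FBtr0079509, 4.35 for FBtr0072462 and -2.94 for FBtr0072463. For ElavC155 minus Elav they were -5.20 for FBtr0082093, -3.04 for FBtr0078518 and 2.22 for FBtr0072463. For ATM8 minus Repo they were 5.48 for FBtr0080464, 3.36 for FBtr0073937, -5.41 for FBtr0082093, -4.06 for FBtr0082765, -7.58 for FBtr0070073, -4.81 for FBtr0081033 and 3.26 for FBtr0079509. The adjusted p of these differences ran up to 0.0064, for FBtr0072463 in ElavC155 minus Elav.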

How the results depend on the processing

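The crossed pairing of the Repo samples and the block of replicates 1 and 2 against 3 and 4 were chosen after the data had been seen. No transcript named for its size changed sign under the alternatives that kept it (4 of them were among the dimmest 25% left out), and for the named genes 46 of 846 alternative values did, none past the threshold in either fit, 42 of them with an array left out. Rises outnumbered falls for ElavC155 (51 and 27) but not without ElavC155-ATMi replicate 2 (11 and 21), nor for ATM8 without heterozygote replicate 2 (47 and 51). In a fit of only the compared arrays the counts were 119 for ATM8, 115 for Elav, 6 for ElavC155, 183 for Repo minus Elav and 8 for ElavC155 minus Elav. With array weights they were 1118 for Repo, 194 for ElavC155, 351 for Repo minus ElavC155 and 23 for ElavC155 minus Elav. Without the dimmest 25% the Elav count was 143, and after quantile normalization that of ElavC155 minus Elav was 7. The cause was not tested for these.

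With each array left out in turn, the counts ran from 98 to 132 for ATM8, 262 to 486 for Repo, 171 to 231 for Elav, 32 to 56 for ElavC155, 134 to 318 for Repo minus Elav, 71 to 166 for Repo minus ElavC155, 6 to 41 for ElavC155 minus Elav and 148 to 209 for ATM8 minus Repo. Where 1 sample was left in a group, it was assumed to vary like the other groups.

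With the replicate block, the count of ElavC155 minus Elav was 31 and that of Elav 322, and in the Elav comparison CG31178 passed (adjusted p = 0.037). It changed no other call of a transcript named in the Elav comparison. In ATM8 and ElavC155 the samples share only a number (same-number correlations 0.26 and 0.51), and the block gave 276 and 103. In Repo that correlation was -0.14, and the block gave 779 and the crossed pairing 875. Of the 24 camera tests, 14 passed with the preset correlation and 14 with the estimated one, and with the block 14 and 11.

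Over the named transcripts, 192 of 196 alternative values for the 16 largest changes kept their call and 4 lost it, and 844 of 846 for the named genes kept theirs and 2 gained it. The 16 were picked for their size and the named genes had no call to lose, so this says little about other calls. In fits of only the compared arrays, 81 of the 246 ATM8 calls were kept, 317 of 658 for Repo, 112 of 250 for Elav and 5 of 78 for ElavC155. With the replicate block, 190, 541, 220 and 63 were kept. The correlation of fold changes moved to 0.283 for Repo and Elav and to 0.435 for Elav and ElavC155 without the dimmest 25%. The tests of gene lists and the choice of the brightest row per gene were not run, since genes could not be matched to rows. Signal over background limits the dim transcripts, whose floor is unknown.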

Other observations

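Both tests of the 20 transcripts changed in all RNA interference comparisons were chosen after their values had been seen.

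The 20 transcripts that changed in the same direction with the Repo, Elav and ElavC155 drivers had a median size of 1.51 on the log2 scale under RNA interference. Their median log2 fold change in ATM8 homozygotes, signed by the direction under RNA interference, was -0.023 (bootstrap interval over transcripts -0.19 to 0.11). It lay below the 0.38 that 25% of the size under RNA interference would be. In these samples this argues only against a response that ATM8 homozygotes share at 25% or more of its size under RNA interference. Whether the 20 transcripts respond to lowered ATM function however it is made cannot be decided here. The ATM8 flies were reared at a lower temperature than the RNA interference flies and were compared with heterozygotes. The level of tefu was not analysed, so the extent of ATM loss is unknown in both kinds of flies. The interval resampled the 20 transcripts, which are not independent, so it leaves out the spread between the ATM8 samples. A contribution of the transgene's chromosome or of strain background cannot be told apart from RNA interference, because the controls lack the transgene in all 3 comparisons. The same transcripts spread more between the 4 control genotypes than others of like level (median SD of the control means 0.607 against 0.378 after quantile normalization of all arrays, percentile 99.9 among 10000 random sets), which may come from strain differences or from genes that vary with conditions. A response to RNA interference itself, or to ATM loss that ATM8 does not share, stays open and untested.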
